A study of Mus musculus with 4 samples.

How the data were processed

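The measurements were single-cell RNA profiles of 4 tumours grown in mice from MOC1, a cell line of mouse oral squamous cell carcinoma. Per the labels, 2 of the tumours had responded and 2 had not responded to antisense oligonucleotides against Smyd3, a lysine methyltransferase, given together with an antibody that blocks the inhibitory T-cell receptor PD-1. The tumours were dissociated to single cells by machine and enzyme, and libraries were made in droplets with 10x Genomics 3′ v3.1 chemistry. The submitters' processing notes list Cell Ranger 7.0.0, bcl2fastq 2.20.0, STAR 2.7.2a and the mouse genome build mm10, without stating the role of each.

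The values deposited by the authors are raw counts of unique molecular identifiers (UMIs) per gene and cell barcode, not normalised. The deposited matrices cover 32285 genes and the barcodes that had already been called as cells, and reads and empty droplets were not available. The counts were whole numbers in every library. In 40 cases a symbol was shared by more than 1 gene identifier, and these genes were kept apart by identifier. Gene coordinates were taken from the GENCODE vM21 annotation of mm10.

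Depth per tumour was 133845871 UMIs over 10398 barcodes in responder 1, 130282787 over 10591 in responder 2, 116222083 over 13821 in non-responder 1 and 204732904 over 16075 in non-responder 2. A barcode was kept with at least 300 genes, at least 500 UMIs and under 15% of its UMIs from mitochondrial genes. Doublets, which are droplets holding more than 1 cell, were scored with Scrublet through scanpy at an expected rate of 0.8% per 1000 barcodes. The planned rule used Scrublet's automatic threshold unless it called under 0.5% of barcodes, in which case the highest scores were removed at the expected rate. This worked unevenly: the automatic threshold was used in non-responder 1 and removed 59 barcodes (0.540%), whereas the expected rate was used in the other tumours and removed 754 barcodes in responder 1 (7.90%), 771 in responder 2 (7.97%) and 1316 in non-responder 2 (11.0%). The rule was kept as planned, and a version with the expected rate in every tumour was added after seeing the data. The cells kept numbered 8785 and 8900 in responders 1 and 2, and 10872 and 10671 in non-responders 1 and 2.

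Counts were scaled to 10000 per cell and log-transformed, 2000 variable genes and 30 principal components were used, and cells were joined to their 15 nearest neighbours and clustered with the Leiden method at resolution 1, which gave 28 clusters. No correction between tumours was applied. Each cluster was named by the mean standardised level of fixed marker lists, and T-like clusters were clustered again and named by subset lists. The marker lists were fixed in advance. The scoring rule was revised after looking at the clusters: a name requires at least 3 markers and 1/3 of the list seen in 20% of the cells, no other class with more markers among the 10 genes that set the cluster apart, and a marker among those genes or a margin of 0.3 to the next class. Names are given as "like" classes, because they rest on transcripts alone. T or NK subclusters that met no subset's rule were left unresolved.

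For each class with at least 20 cells in every tumour, counts were summed per tumour, so that tumours and not cells were the replicates. Genes were tested between responders and non-responders with the quasi-likelihood test of edgeR 4.0.16 after its filter on low counts (filterByExpr) and TMM scaling, at a Benjamini-Hochberg adjusted p under 0.05. Levels are given in CPM, the UMIs of a gene divided by the TMM-scaled library size and multiplied by 1e+06, with the standard deviation (SD) between the tumours of a group. Fold changes are responder over non-responder on the log2 scale, with the standard error (SE) of the fit. The main classes were the epithelial-like, CD8 T-like, regulatory T (Treg)-like, mononuclear phagocyte-like and fibroblast-like cells. The neutrophil-like class was added after seeing the data, as were the CD4 T-like, natural killer (NK)-like, dendritic-like and endothelial-like classes and the choice of lists tested in them.

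The 28 gene lists were tested with camera of limma 3.58.1 on log2 CPM (prior count 2) at a preset correlation between genes of 0.01, with adjustment over the lists of a class and at least 5 tested members per list. Camera with an estimated correlation and fry, which asks whether a list's genes move on balance in 1 direction, were run beside it. Abundance was tested with the edgeR quasi-likelihood test on cell numbers per class, with all kept cells of a tumour as its library size. The ratio of CD8 T-like to Treg-like cells was compared with a two-sided exact permutation test, which cannot go below 0.333 with 2 tumours against 2. Intervals of shares are exact binomial 95% intervals and cover counting error only.

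Genes were named by a rule. In each main class, among genes with an adjusted p under 0.05, a mean of at least 10 CPM and both responder values on the same side of both non-responder values, the 10 with the largest fold change in each direction were named, or all of them where fewer than 5 passed in a direction. List members past the threshold were added, up to 4 per list by adjusted p, as were genes of a fixed panel per class whatever their result, with Smyd3 in every panel. The ranking left out genes whose names begin with Gm and a digit or end with Rik, and T-cell receptor, immunoglobulin, haemoglobin, ribosomal protein and mitochondrial genes. Where no gene passed, the 5 up and 5 down with the smallest p were named as values that did not pass. Genes outside the rule are marked where they appear. The comparisons, tests, gene lists, marker lists, panels, naming rule for genes and most alternatives were chosen before the data were examined.

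The fit was tested on simulated data that had the depth and spread of each class and 200 changed genes. Of genes changed by a log2 of 2, it recovered 21.0% in epithelial-like cells, 97.0% in CD8 T-like cells, 99.0% in Treg-like cells, 87.0% in mononuclear phagocyte-like cells, 55.6% in fibroblast-like cells and 67.0% in neutrophil-like cells. At a log2 of 1 the shares were 0, 32.0, 42.0, 24.0, 5 and 8% in the same order. False calls made up 25.0, 5.84, 6.62, 8.26, 3.23 and 10.7% of the calls.

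The alternatives chosen with the design were RLE scaling, no scaling beyond the total count, no filter on low counts, mitochondrial limits of 10% and 25%, a minimum of 1000 UMIs, doublets kept, Leiden resolutions of 0.5 and 2, counts thinned to the smallest total, the replicate numbers as a block, each tumour left out in turn, and DESeq2 1.42.0 and limma voom in place of edgeR. Gene and list tests were not run at the mitochondrial limit of 25% or at Leiden resolution 2. For abundance, TMM over classes and immune cells alone were also tried. Added after seeing the data were doublets removed at the expected rate in every tumour, cells without barcodes that had under 10% of the UMIs of the same barcode in another library, and classes without clusters of low depth (a median under 1/3 of the tumour's median). The alternatives for neutrophil-like cells were likewise added later.

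Software was Python 3.11.15 with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, scanpy 1.11.5, igraph 0.11.9, leidenalg 0.10.2, umap-learn 0.5.12, scikit-learn 1.9.0 and matplotlib 3.10.9, and R 4.3.3. Classes with under 20 cells in any tumour (B-like, gamma-delta T-like, mast or basophil-like and erythroid-like) were left out of the gene tests for lack of cells, and the unresolved T or NK cells because they hold no single class.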

Results

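Single-cell RNA profiles were collected from 4 MOC1 tumours, grown from a mouse oral squamous carcinoma cell line in the flank of C57BL/6 mice. All 4 tumours had received Smyd3 antisense oligonucleotides with an anti-PD-1 antibody for 29 days, and 2 had responded while 2 had not. Tumours that received control oligonucleotides were not analysed here. Depth ranged from 116222083 UMIs in non-responder 1 to 204732904 in non-responder 2, with 133845871 in responder 1 and 130282787 in responder 2. The analysis kept 39228 cells, with a median of 3617 UMIs per cell in responder 1, 3403 in responder 2, 3467.5 in non-responder 1 and 3270 in non-responder 2. The labels number the tumours but do not state that each came from a separate mouse, so the p-values measure the spread between these samples, which is partly technical if they did not.

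Some cell barcodes occurred in more than 1 library. Of the 50885 barcodes, 4748 (9.33%) held under 10% of the UMIs of the same barcode in another library, and together they held 0.742% of all UMIs. Among kept epithelial-like cells such barcodes were 4078 of 12646 (32.2%), with 1.14% of the UMIs of that class, while among neutrophil-like cells they were 0.0852%. Sums of counts per class were therefore little affected, but shares of epithelial-like cells were.

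**Figure D1:**
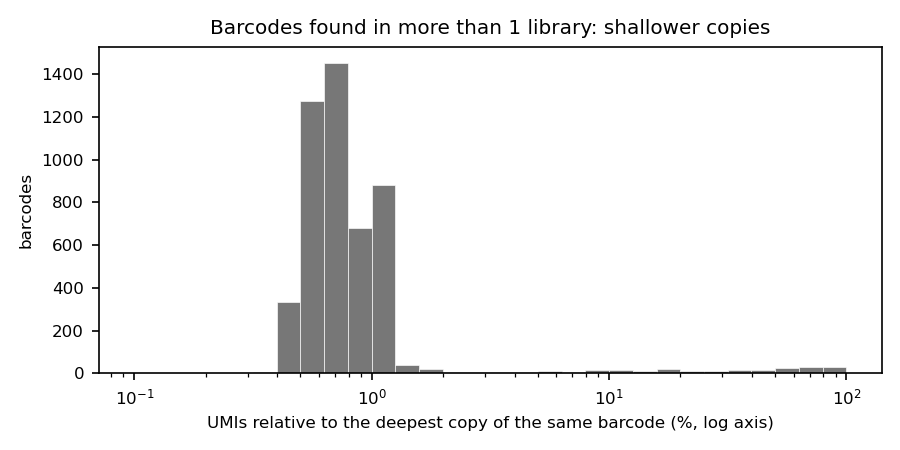
Histogram of the UMIs of a barcode as a percentage of the UMIs of its deepest copy in another library (log axis), for barcodes found in more than 1 library. Most copies lie far below the deepest one, and for those under 10% the median was 0.710%.

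Smyd3, the target of the oligonucleotides and a lysine methyltransferase of histones and signalling proteins, was detected in most cell classes of both groups. In epithelial-like cells, the class that holds the carcinoma cells, its level was 7.58 CPM ± 4.18 (SD, n = 2) in responders and 6.02 ± 2.55 (n = 2) in non-responders. In CD8 T-like cells, the cytotoxic lymphocytes, it was 14.4 ± 2.06 against 17.4 ± 6.59, and in fibroblast-like cells 11.8 ± 2.91 against 13.1 ± 0.781. Mononuclear phagocyte-like cells, meaning monocytes and macrophages, held 3.17 ± 0.128 against 3.58 ± 1.45.

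The Smyd3 gene (ENSMUSG00000055067, mm10 chromosome 1, 178951960 to 179518041, minus strand) did not differ between the groups by edgeR in any of the 7 classes tested, with an adjusted p over classes of 0.740 in each. The log2 fold change in epithelial-like cells was 0.33 (SE 0.53), and it was −0.37 without responder 2, −0.05 without non-responder 1, 0.80 without responder 1 and 0.90 without non-responder 2. Smyd3 UMIs were found in 8.04% and 10.0% of the epithelial-like cells of responders 1 and 2 and in 7.26% and 15.4% of those of non-responders 1 and 2, at median depths of 2817.5, 1311, 10639 and 4831.5 UMIs. In neutrophil-like cells, which served as a background for free RNA, the shares were 0.368, 0.837, 0.388 and 0.700% at median depths of 2747, 3166, 3171 and 2878. Treg-like cells held 0, 3, 5 and 1 Smyd3 UMIs in the 4 tumours, and Smyd3 was not tested in Treg-like, dendritic-like and endothelial-like cells because of its low counts.

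Epithelial-like cells were compared to ask how the epithelial part of responding tumours, carcinoma cells included, differed from that of non-responding ones. Trf, which encodes the iron carrier transferrin, had a mean of 166 CPM ± 5.54 (SD, n = 2) in responders and 5.50 ± 1.74 (n = 2) in non-responders, a 30.1-fold higher mean. Its UMIs in responders lay mostly in 1 group of cells, which was spread unevenly over the tumours. The chemokines Cxcl9 and Cxcl10, which interferon gamma induces and which attract T cells through Cxcr3, had means of 667 ± 82.5 and 418 ± 117 CPM in responders and 150 ± 88.9 and 105 ± 42.5 CPM in non-responders. Genes of the interferon gamma response were higher as a group by camera at its preset correlation, in 36 of 37 members, but not with an estimated correlation (adjusted p 0.723). No single gene passed the threshold, so these are values that did not pass.

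Of 16182 genes tested in epithelial-like cells, 0 passed in edgeR, 1031 had an unadjusted p under 0.05, DESeq2 called 193 (165 up, 28 down) and limma voom 0. Trf (ENSMUSG00000032554, chromosome 9, 103204001 to 103230444) had a log2 fold change of 4.91 (SE 0.35, adjusted p 0.348), and it passed without non-responder 1 (4.62) or non-responder 2 (5.33), with doublets kept (4.94), with no filter on low counts (4.90) and by DESeq2. At Leiden resolution 2, in a look at clusters chosen after its values were seen, a cluster marked by Wfdc18, Krt18 and Aqp5, genes of glandular epithelium, held 93.9 and 93.6% of the Trf UMIs of epithelial-like cells in responders 1 and 2, with 198 and 97 cells there and 2 and 73 cells in non-responders 1 and 2. In that cluster Trf was at 1048 and 1195 CPM in responders 1 and 2 and at 144 in non-responder 2, and without the cluster it was at 15.8 and 14.2 CPM in responders and 3.46 and 2.97 in non-responders. A shallow cluster with the same markers held 103, 102, 64 and 89 Trf UMIs in responders 1 and 2 and non-responders 1 and 2. Trf there was at 693 and 893 CPM in responders and 1079 and 737 in non-responders, so the groups overlapped. At resolution 1, without the cluster with most Trf UMIs, it was at 75.7 and 71.6 CPM against 4.99 and 2.74. All these values are without TMM scaling. At resolution 2, clusters of 1460 and 957 cells that scored best as epithelial stayed unnamed and were left out. In mononuclear phagocyte-like cells Trf lay the other way, at 197 CPM in responders and 320 in non-responders, without TMM scaling. The other genes with the smallest p on the responder side were Espn (57.7 against 11.2 CPM), which bundles actin, Sema3b (41.1 against 8.84), a secreted guidance cue, Mgst1 (33.9 against 7.91), which detoxifies lipids, and the small GTPase Rhoj (18.1 against 3.84). On the non-responder side they were Calca (2.92 against 42.3 CPM), which encodes calcitonin and a related neuropeptide, the amino acid transporter Slc7a8 (6.46 against 30.7), the phosphodiesterase Pde3b (6.87 against 25.5), Castor2 (5.17 against 17.3) and Ttc9 (11.1 against 30.1), whose product is little characterised. Their log2 fold changes ran from −3.86 for Calca to 2.37 for Espn, with adjusted p of 0.649 for all but Calca (0.654). The groups did not overlap for 6013 genes (37.2%), where chance gives 33.3%.

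Cxcl9 (ENSMUSG00000029417, chromosome 5, 92321347 to 92328079) had a log2 fold change of 2.16 (SE 0.49, adjusted p 0.689) and Cxcl10 of 2.00 (SE 0.41, adjusted p 0.657) in epithelial-like cells. The epigenetic regulator Uhrf1 was at 44.0 CPM in responders and 24.9 in non-responders (log2 0.82), the proliferation marker Mki67 at 142 and 92.5 (log2 0.62), and the peptide transporter Tap1 at 408 and 185 (log2 1.14). The interferon-induced Isg15 was at 271 and 171 CPM (log2 0.67) and the antigen-presenting H2-K1 at 3356 and 2281 (log2 0.56). B2m, its light chain, was at 3381 and 2950 CPM (log2 0.20), the checkpoint ligand Cd274 at 169 and 159 (log2 0.09), and the basal keratin Krt14 at 7199 and 6117 (log2 0.24). None of these passed, and their adjusted p ran from 0.761 for Uhrf1 to 0.992 for Cd274.

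**Figure D2:**
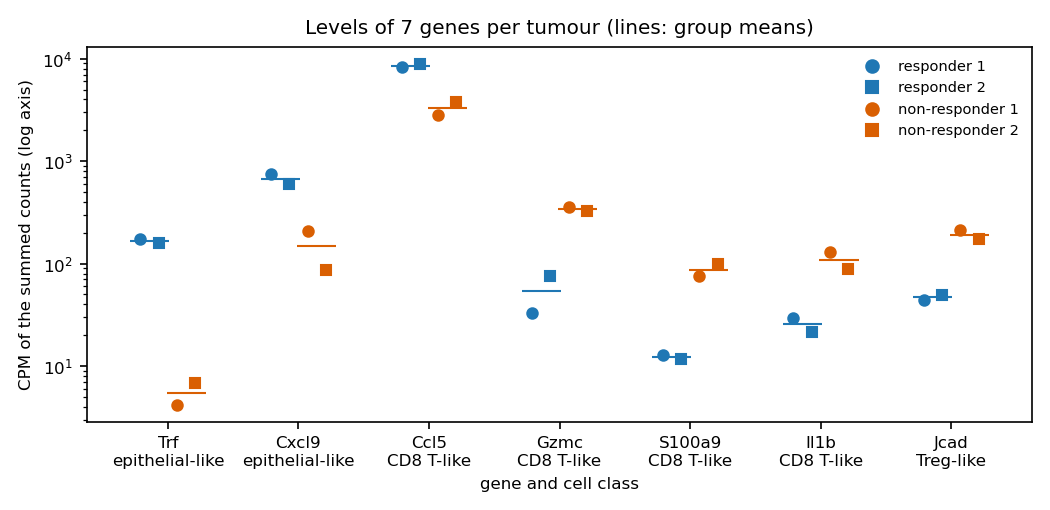
Level of Trf and Cxcl9 in epithelial-like cells, of Ccl5, Gzmc, S100a9 and Il1b in CD8 T-like cells and of Jcad in Treg-like cells (CPM, log axis), with a point per tumour and a line at each group mean. Values are without TMM scaling. Trf lies at 166 CPM in responders against 5.48 in non-responders, and S100a9 at 12.3 against 87.2.

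Of 16 gene lists tested in epithelial-like cells, 7 passed with camera at its preset correlation, 6 of them higher in responders. These were interferon gamma response (median log2 0.97), type I interferon response (0.57, 39 of 47 members higher), MHC class I presentation (0.79), MHC class II presentation (1.97), cell proliferation (0.70, all 46 members higher) and T-cell transcripts from other cells (1.69, a measure of free or doublet RNA). The basal keratinocyte list was lower (−0.28, adjusted p 0.0495). None held with an estimated correlation, where the lowest adjusted p was 0.723, or with fry, where it was 0.802. Over all genes 0 members of these lists passed; adjusted over the list alone, 3 genes of the interferon gamma list, 7 of the MHC class II list and 7 of the T-cell transcript list were higher. In the lists that did not pass, adjusted over the list alone, 3 T-cell attracting chemokines and 2 keratinocyte differentiation genes were higher.

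The epithelial lists that did not pass were epithelial-mesenchymal transition (median −0.36), hypoxia (0.01), dissociation and immediate early genes (−0.23), myeloid attracting chemokines (−0.37), myeloid transcripts from other cells (−0.26) and 4 lists whose median, mean and test differed in sign. These 4 were keratinocyte differentiation (test up, median −0.39, mean −0.18), T-cell attracting chemokines (test up, median −0.12, mean 0.23), checkpoint ligands (test down, median −0.17, mean 0.07) and stromal transcripts from other cells (test up, median −0.36, mean −0.07). The mean log2 level of the interferon gamma list was 6.84 in responder 1, 5.88 in responder 2, 6.10 in non-responder 1 and 4.07 in non-responder 2, so that the groups overlapped.

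Single tumours moved the epithelial results. The median of the interferon gamma list was 0.31 without responder 1, 0.29 without non-responder 2, 2.63 without non-responder 1 and 1.46 without responder 2. The type I interferon list no longer passed without responder 1 (−0.32), passed as lower without non-responder 2 (−0.06) and reached 0.97 without responder 2 and 2.19 without non-responder 1, and the basal keratinocyte list no longer passed without responder 2 (−0.23) or non-responder 2 (0.08). The MHC class I list was 0.27 without non-responder 2 and 1.84 without non-responder 1, the MHC class II list 1.24 without responder 1, and the proliferation list 0.36 without responder 2. The number of genes past the threshold was 0 without either responder, 966 without non-responder 1 and 268 without non-responder 2, in fits that assume the lone tumour of a group to vary like those of the other. The cluster with the most epithelial-like cells of non-responder 1 was cluster 11 (30.4%), followed by cluster 0 (27.1%), and cluster 0 held the most in responder 1 (27.1%), responder 2 (35.2%) and non-responder 2 (31.5%). Cluster 0 was shallow, at a median of 0.264 of the tumour's median UMIs. These shares of cells therefore do not show which clusters set the summed counts.

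**Figure D3:**
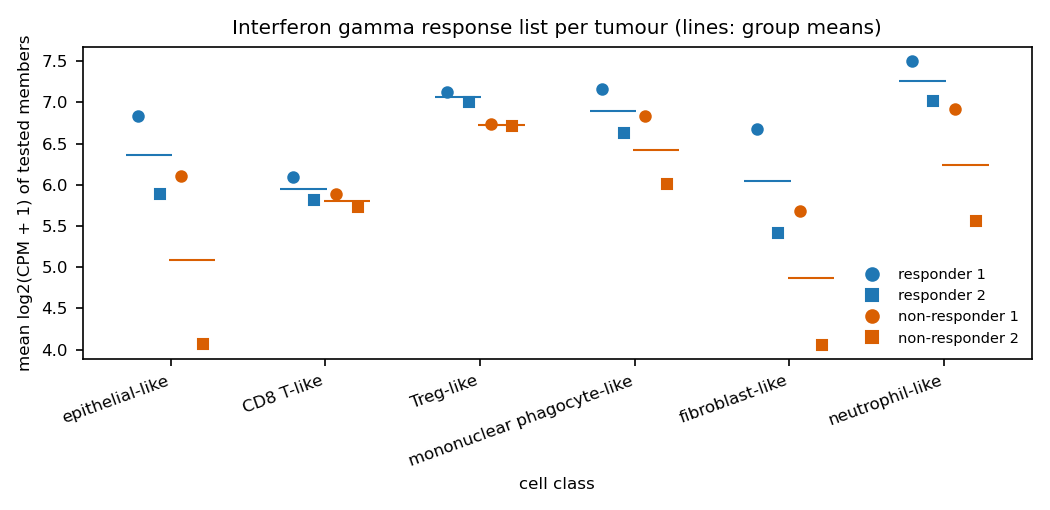
Mean log2(CPM + 1) of the tested members of the interferon gamma response list in 6 cell classes, with a point per tumour in each group. In epithelial-like cells non-responder 2 lies at 4.07 while the other 3 tumours lie between 5.88 and 6.84.

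CD8 T-like cells were compared to ask how the cytotoxic lymphocytes differed with the response. S100a9 and S100a8, which encode the calprotectin subunits typical of neutrophils, fell by 2.75 and 2.72 on the log2 scale in responders, to 12.7 CPM ± 0.0300 and 11.2 ± 3.02 (SD, n = 2) from 87.0 ± 23.8 and 75.6 ± 32.6 (n = 2) in non-responders. Il1b, which encodes the inflammatory cytokine interleukin 1 beta, fell by 2.03, to 26.2 ± 4.13 from 107 ± 20.5 CPM. The chemokine Ccl5 and the granzyme Gzmc, chosen after their values were seen, had means of 8835 and 56.6 CPM in responders and 3315 and 338 CPM in non-responders and did not pass.

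In edgeR, 3 of 9593 genes passed in CD8 T-like cells, all lower in responders: S100a9 (SE 0.27, adjusted p 0.00890), Il1b (SE 0.24, adjusted p 0.0212) and S100a8 (SE 0.35, adjusted p 0.0326). S100a9 (ENSMUSG00000056071, 90692632 to 90695721) and S100a8 (ENSMUSG00000056054, 90668978 to 90670035) are neighbours on chromosome 3, and Il1b (ENSMUSG00000027398) lies on chromosome 2 at 129364570 to 129371139. In neutrophil-like cells S100a8 was at 11629 CPM in responders and 10343 in non-responders, without TMM scaling, and the neutrophil share differed between the groups, so free RNA or mixed droplets are an open source of these counts. S100a8 and Il1b no longer passed when doublets were removed at the expected rate in every tumour (−2.86 and −1.85) or without shared barcodes (−2.68 and −1.92), and Il1b did not when doublets were kept (−1.85). DESeq2 called 17 genes and limma voom 4, each including these 3, and 491 had an unadjusted p under 0.05. The groups did not overlap for 3242 genes (33.8%, chance 33.3%).

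Gzmc (ENSMUSG00000079186, chromosome 14, 56231441 to 56234656) had a log2 fold change of −2.58 (SE 0.36, adjusted p 0.0577) and Ccl5 (ENSMUSG00000035042, chromosome 11, 83525778 to 83530518) of 1.42 (SE 0.38, adjusted p 0.639) in CD8 T-like cells. The checkpoint receptor Pdcd1, whose protein the antibody binds, was at 539 CPM ± 32.0 in responders and 413 in non-responders (log2 0.38). The exhaustion regulator Tox was at 279 and 222 CPM (log2 0.32), the checkpoint receptor Havcr2 at 202 and 164 (log2 0.28), and the stem-like T-cell factor Tcf7 at 62.0 and 101 (log2 −0.69, SE 0.26). The granzyme Gzmb was at 932 ± 423 and 1112 ± 784 CPM (log2 −0.26) and Ifng, which encodes interferon gamma, at 144 and 138 (log2 0.05). The adjusted p of these 6 ran from 0.918 for Tcf7 to 0.992 for Ifng, and Ifng turned sign under several of the settings tried.

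Of 10 lists tested in CD8 T-like cells, 4 passed: type I interferon response (median 0.22) and T-cell exhaustion (0.30, 22 of 28 members higher) were higher, and stromal (−1.17) and myeloid transcripts from other cells (−0.08, mean −0.40) were lower in responders. None held with an estimated correlation (lowest adjusted p 0.576) or with fry (0.582). The median mitochondrial share of CD8 T-like cells was 5.01 and 4.78% in responders 1 and 2 and 7.98 and 7.21% in non-responders 1 and 2, and under 10% mitochondrial UMIs 1 list passed, without the type I interferon (0.09) and myeloid lists (0.09). The type I interferon list also lost its call with doublets kept (0.03), at Leiden resolution 0.5 (0.09) and without shared barcodes (0.11). Over all genes 2 members of the myeloid list passed, and adjusted over the list alone 4 did; 1 exhaustion gene was higher adjusted over the list alone. In lists that did not pass, adjusted over the list alone, 2 interferon gamma genes were higher and 1 lower, 1 cytotoxic effector was higher and 1 lower, and 1 dissociation gene was lower. Those lists were interferon gamma response (0.09), cytotoxic effectors (−0.07), naive and memory T cells (−0.27), cell proliferation (0.13), dissociation and immediate early genes (−0.14) and epithelial transcripts from other cells (test down, median 0.01, mean −0.13). Without responder 1 the exhaustion (0.15) and type I interferon lists (0.10) no longer passed, nor did the stromal list (−0.60), and without non-responder 2 the exhaustion list (0.14) and the stromal list (0.25) did not; the myeloid list had a median of 0.17 without responder 1, −0.64 without responder 2, −0.16 without non-responder 1 and −0.23 without non-responder 2. Leaving out responder 1, responder 2, non-responder 1 or non-responder 2 gave 39, 35, 65 and 141 genes, the 3 named ones among them each time.

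Treg-like cells, the Foxp3-expressing cells that restrain other T cells, were compared with the same question. Jcad, which encodes a junctional protein known from endothelial cells, fell by 2.00 on the log2 scale (SE 0.25, adjusted p 0.0422 by edgeR), to 48.8 CPM ± 5.78 (SD, n = 2) in responders from 197 ± 15.01 (n = 2) in non-responders. Foxp3 itself was at 586 CPM ± 54.5 in responders and 574 ± 15.6 in non-responders. Genes of the interferon gamma response were higher as a group in responders by camera at its preset correlation (median log2 0.27, 26 of 30 members), but not with an estimated correlation (adjusted p 0.250). The median mitochondrial share of these cells, a sign of RNA quality, was 4.81 and 5.06% in responders 1 and 2 and 8.83 and 7.42% in non-responders 1 and 2.

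Jcad (ENSMUSG00000033960, chromosome 18, 4634878 to 4682869) was the 1 gene of 7068 that passed in Treg-like cells by edgeR, and limma voom called 1 gene and DESeq2 6, each including Jcad, while 379 had an unadjusted p under 0.05. Its level without TMM scaling was 147 and 142 CPM in endothelial-like cells of responders and non-responders and 1.06 and 0.904 in mononuclear phagocyte-like cells. At a Leiden resolution of 0.5 Jcad kept a log2 fold change of −2.003 and did not pass. The growth factor receptor subunit Il2ra was at 1277 and 1692 CPM (log2 −0.41), and the checkpoint receptor Ctla4 was at 2461 and 1861 (log2 0.40). The costimulatory receptor Tnfrsf4 was at 1972 and 1527 (log2 0.37) and Foxp3 had a log2 fold change of 0.03, with adjusted p from 0.929 to 0.994 for these 4. The groups did not overlap for 2377 genes (33.6%, chance 33.3%).

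Of 8 lists tested in Treg-like cells, 5 passed: interferon gamma response, type I interferon response (median 0.19) and cell proliferation (0.18) were higher, and dissociation and immediate early genes (−0.23) and epithelial transcripts from other cells (−0.61) were lower. None held with an estimated correlation (lowest adjusted p 0.250) or with fry (0.335). Over all genes 0 list members passed; adjusted over the list alone, 2 interferon gamma genes were higher, 3 dissociation genes were lower, 1 Treg effector gene was lower, and of the myeloid transcripts 1 was higher and 3 were lower. The lists that did not pass were the Treg effector programme (−0.07), myeloid transcripts from other cells (−0.09) and naive and memory T cells (test up, median −0.03, mean −0.09). The type I interferon list no longer passed without responder 1 (−0.03) or non-responder 1 (0.06), the proliferation list without responder 1 (0.07) or non-responder 2 (0.003471), and the dissociation list without non-responder 2; the epithelial list was −0.30 without responder 1. Leaving out responder 1, responder 2, non-responder 1 or non-responder 2 gave 14, 16, 41 and 59 genes, Jcad among them.

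Mononuclear phagocyte-like cells were compared because macrophages can restrain or attract T cells. The transcription factor Sox4 was at 17.4 CPM ± 0.258 (SD, n = 2) in responders and 63.3 ± 14.99 (n = 2) in non-responders, and Cd40, the receptor through which T cells activate macrophages, at 107 ± 30.7 and 51.9 ± 11.3. Cxcl9 was at 1048 ± 554 in responders and 451 ± 18.8 in non-responders, and the matrix protein gene Spp1 at 931 ± 21.5 and 2367 ± 2337. Members of the interferon gamma response list were higher in 35 of 36 cases, and myeloid attracting chemokines were lower as a group, both by camera at its preset correlation but not with an estimated one (adjusted p 0.479 for each). The median mitochondrial share of these cells was 4.98 and 4.76% in responders 1 and 2 and 6.08 and 6.46% in non-responders 1 and 2, and T-cell transcripts from other cells were higher in all 18 members, with a larger median (0.87) than the interferon gamma list (0.36). No single gene passed.

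Of 12538 genes tested in mononuclear phagocyte-like cells, 0 passed in edgeR, 540 had an unadjusted p under 0.05, DESeq2 called 40 (3 up, 37 down) and limma voom 0. The smallest p on the responder side belonged to the activating receptor Klrk1 (36.5 against 17.3 CPM), the chaperone Hspa2 (19.5 against 10.1), the zinc exporter Slc30a1 (61.9 against 38.8), Cd40 (log2 1.04) and the membrane protease Mmp25 (32.3 against 15.9). On the other side they belonged to Sox4 (log2 −1.86), the adaptor Apbb2 (8.63 against 27.8), the protease inhibitor Serpinb6a (30.4 against 74.9), Maged1 (5.41 against 16.5), a regulator of cell death, and the histone gene Hist1h2bc (26.5 against 62.6). Their adjusted p ran from 0.476 for Sox4, Apbb2 and Serpinb6a to 0.990 for Mmp25. Klrk1 is also one of the fixed NK markers, and RNA from NK or T cells was not excluded as its source. The arginase gene Arg1 was at 702 and 1000 CPM (log2 −0.51), the complement gene C1qa at 2775 and 2822 (log2 −0.02), H2-Aa of MHC class II at 6718 and 5116 (log2 0.39), Cd274 at 301 and 295 (log2 0.03) and Il1b at 2929 and 3280 (log2 −0.16). Cxcl9 had a log2 fold change of 1.22 (SE 0.39) and Spp1 of −1.35 (SE 0.72), and the adjusted p of these panel genes was 0.996 or 0.997. The groups did not overlap for 3855 genes (30.7%, chance 33.3%).

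Of 17 lists tested in mononuclear phagocyte-like cells, 11 passed. Higher in responders were interferon gamma response (median 0.36), type I interferon response (0.21), MHC class I (0.29) and class II presentation (0.39), cell proliferation (0.13) and T-cell transcripts from other cells (0.87). Lower were myeloid attracting chemokines (−0.66), alternatively activated and tumour macrophage genes (−0.49), complement and lipid macrophage genes (−0.38), dissociation and immediate early genes (−0.26) and stromal transcripts from other cells (−0.84). None held with an estimated correlation (lowest adjusted p 0.479) or with fry (0.0916). Over all genes 0 members passed; adjusted over the list alone, 4 dissociation genes, 3 alternatively activated genes and 1 myeloid chemokine were lower, and of the T-cell attracting chemokines 2 were higher and 3 lower.

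The macrophage lists that did not pass were hypoxia (−0.19), checkpoint ligands (0.13), monocyte genes (0.20), epithelial transcripts from other cells (−0.10), T-cell attracting chemokines (test down, median 0.11, mean −0.28) and inflammatory macrophage genes (test up, median −0.02, mean −0.07). In mononuclear phagocyte-like cells, without responder 1 the type I interferon list passed as lower (−0.11), and the MHC class I (0.05), proliferation (0.04) and stromal lists (−0.32) no longer passed, and the interferon gamma list was 0.07 with its call kept. Without non-responder 2 the interferon gamma (0.11), type I interferon (0.01) and stromal lists (0.08) no longer passed, and without non-responder 1 the myeloid chemokine (−0.23), alternatively activated (0.04) and proliferation lists (−0.06) did not. The gene count was 0 without either responder, 33 without non-responder 1 and 196 without non-responder 2. Responder cells lay mainly in clusters 4 (40.0%) and 8 (34.4%) and non-responder cells in clusters 4 (40.1%) and 10 (23.3%). Cluster 8 was shallow, at a median of 0.2875 of the tumour's median UMIs, against 3.552 in cluster 4 and 2.682 in cluster 10. The share in cluster 8 is therefore one of shallow barcodes, and it does not show a macrophage state particular to responders.

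Fibroblast-like cells were compared because they make the matrix and signals around the carcinoma cells. Saa3, which encodes an acute-phase protein, was at 587 CPM ± 31.8 (SD, n = 2) in responders and 138 ± 36.9 (n = 2) in non-responders, and Trf at 84.4 ± 13.6 and 21.5 ± 3.69. Grem1, which encodes an antagonist of bone morphogenetic proteins, was at 30.2 ± 2.61 and 104 ± 31.1. All 35 tested members of the interferon gamma response list were higher in responders, a list that passed at the preset correlation but not with an estimated one (adjusted p 0.610). No single gene passed.

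Of 11713 genes tested in fibroblast-like cells, 0 passed in edgeR, 356 had an unadjusted p under 0.05, DESeq2 called 12 (5 up, 7 down) and limma voom 0. Besides Saa3 (log2 2.09, SE 0.30) and Trf (log2 1.99), the smallest p on the responder side belonged to the mitochondrial gene Chchd10 (30.3 against 2.27 CPM), Myoc (23.1 against 5.70), which encodes a secreted glycoprotein, and Rarres2 (831 against 205), which encodes the chemoattractant chemerin. On the other side they belonged to Grem1 (log2 −1.78), the imprinted Zim1 (2.35 against 27.9), the phosphatase Alpl (1.45 against 26.9), the collagenase Mmp13 (5.08 against 19.9) and the transcription factor Sp6 (7.16 against 21.6). The collagen gene Col1a1 was at 14690 and 15820 CPM (log2 −0.11), the contractile Acta2 at 1181 and 1273 (log2 −0.11), the matrix gene Postn at 3798 and 3575 (log2 0.09), the chemokine Cxcl12 at 744 and 373 (log2 1.00) and the cytokine Il6 at 247 ± 211 and 71.6 ± 21.1 (log2 1.78). The adjusted p of every gene named for this class was 1.00. The groups did not overlap for 3377 genes (28.8%, chance 33.3%).

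Of 15 lists tested in fibroblast-like cells, 9 passed. Higher in responders were interferon gamma response (median 1.02), type I interferon response (0.33), MHC class I (0.82) and class II presentation (0.23), T-cell attracting chemokines (1.00), inflammatory (0.75) and resting adventitial fibroblast genes (0.89), and lower were hypoxia (−0.24) and contractile and matrix genes (−0.11, mean −0.26). None held with an estimated correlation (lowest adjusted p 0.610) or with fry (0.967). The fibroblast-like cells had a median of 3001 and 4124 UMIs in responders 1 and 2 and 21506 and 32718 in non-responders 1 and 2. At Leiden resolution 2 they fell into a deep cluster marked by Col3a1 and Dcn (61, 96, 69 and 242 cells in responders 1 and 2 and non-responders 1 and 2) and a shallow one marked by Postn and Acta2 (53, 110, 36 and 78 cells). Over all genes 0 members passed; adjusted over the list alone, 2 T-cell attracting chemokines were higher and 1 lower, 1 inflammatory fibroblast gene was higher and 1 lower, 2 contractile genes were lower and 1 dissociation gene was lower. The lists that did not pass were cell proliferation (0.34), dissociation and immediate early genes (0.29), epithelial (−0.23) and myeloid transcripts from other cells (−0.39), myeloid attracting chemokines (test up, median 0.02, mean −0.39) and T-cell transcripts from other cells (test up, median −0.14, mean 0.26).

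In fibroblast-like cells, without responder 1 the type I interferon (0.07), T-cell chemokine (0.67), contractile (−0.01), inflammatory (0.35) and resting adventitial lists (−0.08) no longer passed, and the interferon gamma list was 0.32. Without non-responder 2 the type I interferon (0.07), T-cell chemokine (0.75) and MHC class II lists (−0.46) no longer passed, and the interferon gamma list was 0.38. The MHC class II list also lost its call without responder 2 (0.19), and the hypoxia list without responder 2 (−0.36) or non-responder 1 (−0.17), where the interferon gamma list was 2.33. Leaving out responder 1, responder 2, non-responder 1 or non-responder 2 gave 7, 1, 97 and 41 genes.

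Cell classes were compared by their share of captured cells, to ask which immune cells were found in responding tumours. CD8 T-like cells made up 5.31% ± 0.969 (SD, n = 2) of the cells in responders and 1.53% ± 0.315 (n = 2) in non-responders, and NK-like cells 1.70% and 0.385%. Neutrophil-like cells made up 19.1% ± 8.01 and 49.7% ± 13.5, and mononuclear phagocyte-like cells 24.2% ± 3.33 and 13.5% ± 1.35. Epithelial-like cells, which include many barcodes shared between libraries, made up 37.9% ± 4.32 and 27.7% ± 11.0. Digestion and capture set these shares as well as the tissue. The shares of a tumour are parts of a whole, so a lower neutrophil-like share raises those of other classes. Many mononuclear phagocyte-like cells lay in cluster 8, a cluster of low depth. It held 592 and 878 cells in responders 1 and 2 and 190 and 420 in non-responders 1 and 2. The share of this class, and its difference between the groups, therefore depend in part on shallow barcodes.

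No class passed in the edgeR test over 15 classes, and 5 had an unadjusted p under 0.05: NK-like (log2 2.14, SE 0.68, adjusted p 0.0552), CD8 T-like (log2 1.79, SE 0.65, adjusted p 0.0593), CD4 T-like (log2 1.77, SE 0.66, adjusted p 0.0593), neutrophil-like (log2 −1.38, SE 0.64, adjusted p 0.117) and gamma-delta T-like cells (log2 1.96, adjusted p 0.117). Treg-like (log2 0.94), mononuclear phagocyte-like (log2 0.84), epithelial-like (log2 0.45) and fibroblast-like cells (log2 −0.13) had adjusted p from 0.293 to 0.924. CD8 T-like cells were 6.00% (95% interval 5.51 to 6.52) and 4.63% (4.20 to 5.09) in responders 1 and 2 and 1.76% (1.52 to 2.02) and 1.31% (1.10 to 1.55) in non-responders 1 and 2. T or NK cells that met no subset's rule, a rule revised after seeing the data, made up 2.60 and 2.16% in responders and 1.40 and 0.984% in non-responders. Calls changed with the settings: without shared barcodes the CD8 T-like (log2 1.90), CD4 T-like (1.98) and NK-like classes (1.87) passed, whereas at a mitochondrial limit of 25% CD8 T-like cells passed (2.58) and NK-like cells did not (1.57). At that limit a subcluster of 312 cells that scored best as CD8 T was named NK-like, so names changed as well. The value of CD4 T-like cells was 2.42 without non-responder 1 and 1.33 without non-responder 2, neither past the threshold.

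**Figure D4:**
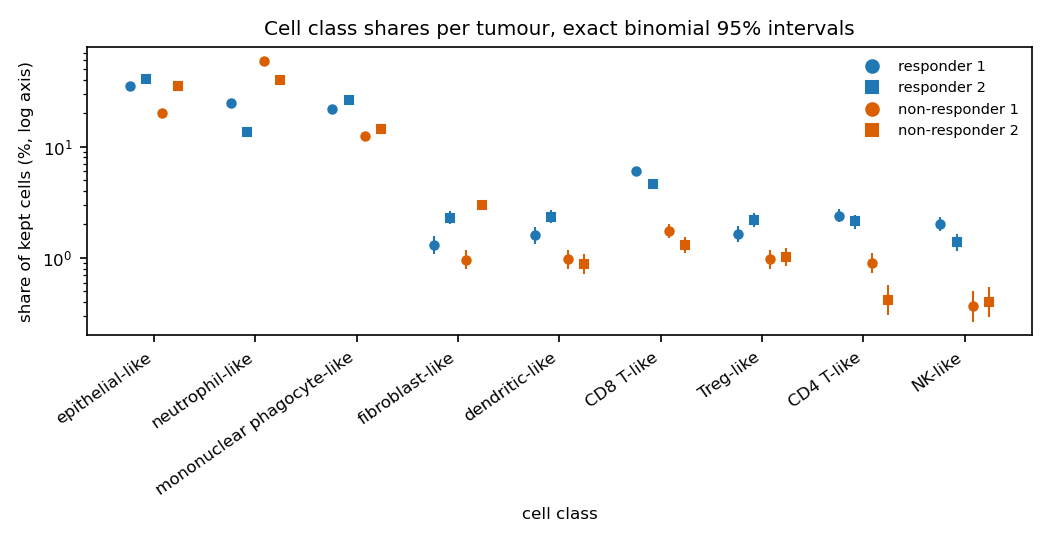
Share of captured cells per class (%, log axis), with a point per tumour and its exact binomial 95% interval. CD8 T-like cells lie at 6.00 and 4.63% in responders and at 1.76 and 1.31% in non-responders.

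The number of CD8 T-like cells per Treg-like cell, a measure of effector over suppressor cells, was 2.89 ± 1.09 (SD, n = 2) in responders and 1.54 ± 0.366 (n = 2) in non-responders. The ratio was 3.66 and 2.11 in responders 1 and 2 and 1.80 and 1.28 in non-responders 1 and 2. The mean log2 ratio was higher by 0.87 in responders, and the two-sided exact permutation p was 0.3333, the smallest that 2 tumours against 2 allow. The difference was 0.47 without responder 1, 0.63 without non-responder 2, 1.11 without non-responder 1 and 1.27 without responder 2. At Leiden resolution 0.5 the groups overlapped in this ratio. CD8 T-like cells then numbered 401 and 191 in responders 1 and 2 and 155 and 93 in non-responders 1 and 2. Treg-like cells numbered 146, 195, 106 and 109 in the same order. A subcluster marked by Ly6c2, Klf3 and Gramd3 was CD8 T-like at resolution 2, but one with these markers was CD4 T-like at resolution 0.5. The ratio therefore depends on how clusters were named.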

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

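The tests of barcodes drawn by chance, free neutrophil RNA (with and without S100a8 and S100a9), RNA quality and a tumour far from the other 3 were chosen after the result was seen. The other 4 tests of this part, on reads of deep cells, on Odam, on droplets holding a neutrophil and a T cell, and on free immune RNA in epithelial droplets, were written down first.

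The shares of 2 kinds of barcode differed between the tumours. Barcodes with many mitochondrial UMIs lay outside the comparisons. Most barcodes shared with a deeper copy in another library (4265 of 4748) were kept cells and lay inside them. Those left out for 15% or more mitochondrial UMIs, a sign of damaged cells, were 7.348 and 7.261% of the barcodes of responders 1 and 2 and 20.16 and 24.04% of those of non-responders 1 and 2. Barcodes with under 10% of the UMIs of the same barcode in another library, seen mostly among epithelial-like cells, were 13.52 and 12.15% in responders 1 and 2 and 5.897 and 7.714% in non-responders 1 and 2. No control library was analysed for either share, and the difference between the groups was not tested.

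Barcodes found in more than 1 library, taken from all classes, had copies of very unequal depth. A draw of the same barcode by separate cells is argued against, because barcodes whose deepest copy was above 20000 UMIs were shared 58.79 times as often as those of 1000 to 5000 UMIs (27.3% against 0.464%). Reads of a deep cell counted in another library stay open as a candidate explanation: the shallow copy matched the deep cell with its barcode best in 99.54% of copies (1287 of 1293), where chance gives 10%. For Odam, an ameloblast gene whose UMIs lay mostly in non-responder 2, 57.92% of the UMIs in epithelial-like cells of the other 3 tumours sat in barcodes shared with that tumour, but so did 45.7% of all those cells, so this test does not tell spill-over from expression. No biological explanation was tested for this pattern.

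S100a8, S100a9 and Il1b were lower in CD8 T-like cells of responders, where neutrophil-like cells made up 19.1% of captured cells against 49.7% in non-responders. Free neutrophil RNA may be the source: the median log2 fold change of the 12 fixed neutrophil markers tested in CD8 T-like cells was −1.866, and that of the 10 other than S100a8 and S100a9 was −1.69, with 9 of 10 lower, among them Cxcl2 (−2.79) and Csf3r (−2.27), and Ifitm1, which T cells also express, higher at 0.55. Markers that missed the filter on low counts are not among them. Some that entered lay low in responders, such as Trem1 (2.61 against 7.78 CPM) and Clec4d (2.26 against 7.88). The filter could admit these through non-responders alone, so the count of lower markers is not independent of it. In NK-like cells the means without TMM scaling of S100a9 (33.1 against 47.1 CPM), Il1b (37.3 against 101.5) and Cxcl2 (30.1 against 229) also lay lower in responders, while S100a8 lay the other way (34.2 against 23.4), on 4 and 7 UMIs in non-responders 1 and 2. Droplets holding a neutrophil and a T cell stay undecided, as cells with 10 or more S100a8 and S100a9 UMIs held 48.06% of the 310 UMIs in non-responders, 25.3% in non-responder 1 and 70.5% in non-responder 2, and without those cells the sums, without TMM scaling, were 18.6 and 24.2 CPM in responders 1 and 2 and 99.6 and 58.4 in non-responders 1 and 2. In Treg-like cells S100a9 (17.8 against 101 CPM) and Il1b (26.2 against 150) had lower means in responders, without TMM scaling. Both also did in CD4 T-like (16.9 against 54.6, 22.4 against 84.8) and endothelial-like cells (16.9 against 200, 51.7 against 163). Means in fibroblast-like and epithelial-like cells lay the same way, but in classes other than T cells the groups overlapped for some genes. The fall was thus not particular to CD8 T-like cells. Expression by the T cells themselves, the biological explanation, stays open and untested.

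The interferon gamma list was higher in responder epithelial-like cells, at a median log2 fold change of 0.97. Free RNA of immune cells is argued against as the whole cause for 6 members only, those with a higher level in epithelial-like cells than in every immune class. They had a median of 0.9722, all 6 higher, from 0.57 to 2.73. The 6 were picked by mean level in the same data, so a gene raised in responder epithelial-like cells could enter more easily. T-cell transcripts from other cells, a measure of free or doublet RNA, rose more in this class (median 1.69), so such RNA may be part of the rise. RNA quality cannot be told apart from the response: the list kept 0.9264 among cells under 10% mitochondrial UMIs, but the groups lie apart in the median mitochondrial share of epithelial-like cells (5.43 and 5.33% in responders 1 and 2, 5.60 and 6.51% in non-responders 1 and 2). Within the class responder 1, with the slightly higher share of the responders, had the higher list level (6.84 against 5.88), which this explanation does not predict. Over all kept cells the median share was 4.783 and 4.791% in responders 1 and 2 and 6.18 and 6.51% in non-responders 1 and 2. By these shares the tumour with the higher value had the lower list level in both groups, which this explanation does predict. In responders both orders rest on small differences in share. A single far tumour also stays undecided, with a median of 0.2895 without non-responder 2 and 0.31 without responder 1, against 1.46 without responder 2 and 2.63 without non-responder 1. A response of the carcinoma cells to interferon in responding tumours remains a hypothesis.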

How the results depend on the processing

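Removing doublets at the expected rate in every tumour, leaving out shared barcodes and leaving out clusters of low depth were tried only after the result was seen. Of the named genes' alternatives, 1075 kept direction and side of the threshold, 91 kept direction and came to pass, 6 lost a call and 33 changed sign. For lists that passed, 520 kept both, 43 lost the call and 8 were reversed, a count that does not cover every sign change of a median. For class abundance 99 kept both, 23 came to pass and 4 changed sign. For Smyd3 35 kept both and 5 changed sign.

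S100a9 stayed lower past the threshold in CD8 T-like cells under every setting run. The number of genes past the threshold there was 3, and it was 6 with no scaling, 96 with no filter on low counts, 10 under 10% mitochondrial UMIs, 5 with doublets kept, 5 at Leiden resolution 0.5, 1 without shared barcodes, 6 with thinned counts and 17 by DESeq2. In Treg-like cells, with 1 gene, it was 13 with no scaling, 52 with no filter, 6 under 10% mitochondrial UMIs, 0 at resolution 0.5, 6 without shared barcodes, 2 with thinned counts and 6 by DESeq2. Where edgeR called 0, epithelial-like cells gave 43 with no filter, 1 with doublets kept and 193 by DESeq2, fibroblast-like cells 220 with no filter and 12 by DESeq2, and mononuclear phagocyte-like cells 40 by DESeq2. Dropping the filter adds genes with few counts to the test; for the other settings the cause was not tested.

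No list in any of the 5 main classes passed with an estimated correlation or fry, a count of 0 in each. These settings do not assume the low preset correlation between genes. In CD8 T-like cells 1 list passed under 10% mitochondrial UMIs. The basal keratinocyte list lay near the threshold and lost its call with no scaling (−0.28), at 1000 UMIs (−0.28) and under 10% mitochondrial UMIs (−0.31). The cause was not tested.

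NK-like, CD8 T-like and CD4 T-like cells, higher in responders but not past the threshold, passed under several settings. The number of classes that passed was 1 with TMM over classes, 9 among immune cells alone, 3 under 10% and 1 under 25% mitochondrial UMIs, 3 without shared barcodes and 3 without clusters of low depth. Among immune cells alone the log2 fold changes were 2.33 for NK-like, 2.01 for CD8 T-like, 2.03 for CD4 T-like, 1.15 for Treg-like, 1.04 for mononuclear phagocyte-like and −1.17 for neutrophil-like cells. Neutrophil-like cells were 39.1 and 24.2% of immune cells in responders 1 and 2 and 75.5 and 66.8% in non-responders 1 and 2. A lower neutrophil share raises the shares of the other immune classes, so these 9 calls are not separate changes. Under 10% mitochondrial UMIs they were 2.33, 2.10 and 2.07 for NK-like, CD8 T-like and CD4 T-like cells, without shared barcodes 1.87, 1.90 and 1.98, and without clusters of low depth 2.42, 2.11 and 2.12. CD8 T-like cells gave 2.58 under 25%, where NK-like cells fell short of the threshold at 1.57, and with TMM over classes neutrophil-like cells gave −2.06. Under 25%, a subcluster of 312 cells marked by Gzmc, Nrn1 and Prf1 was named NK-like although CD8 T scored best. Another of 318 cells, marked by Ly6c2 and also scoring best as CD8 T, was unnamed. A change of names is therefore part of both values under 25%. Epithelial-like cells turned to −0.12 with TMM over classes and fibroblast-like cells to 0.18 without clusters of low depth, and the cause was not tested.

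Ifng, near 0 in CD8 T-like cells, changed sign with no scaling (−0.0139), under 10% mitochondrial UMIs (−0.22), at 1000 UMIs (−0.0116), with doublets removed at the expected rate in every tumour (−0.16), without shared barcodes (−0.0366) and with thinned counts (−0.008569). Foxp3 in Treg-like cells did so with doublets removed at the expected rate (−0.002005), and Postn in fibroblast-like cells with no scaling (−2.762e-05) and with doublets kept (−0.0856). None of these values passed, and the cause was not tested.

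With the replicate numbers taken as a block, CD8 T-like cells gave 83 genes, Treg-like cells 153, fibroblast-like cells 1, and epithelial-like and mononuclear phagocyte-like cells 0. Under the block 9 classes passed in abundance, at 2.12 for NK-like, 1.79 for CD8 T-like, 1.84 for CD4 T-like, 0.93 for Treg-like, 0.84 for mononuclear phagocyte-like and −1.42 for neutrophil-like cells. The labels do not say that equal numbers mean a shared day or cage. As a check of the pairing, the log2 difference of each gene between responders 1 and 2 was correlated with that between non-responders 1 and 2, at 0.342 in epithelial-like, 0.275 in CD8 T-like, 0.281 in Treg-like, 0.295 in mononuclear phagocyte-like and 0.211 in fibroblast-like cells.

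Leaving out 1 tumour assumes that the lone tumour of a group varies like the other group, and the tumour behind each end is named. The gene counts ran from 0 (without either responder) to 966 (without non-responder 1) in epithelial-like cells, from 35 (without responder 2) to 141 (without non-responder 2) in CD8 T-like cells, from 14 (without responder 1) to 59 (without non-responder 2) in Treg-like cells, from 0 (without either responder) to 196 (without non-responder 2) in mononuclear phagocyte-like cells and from 1 (without responder 2) to 97 (without non-responder 1) in fibroblast-like cells. The list counts ran from 7 to 13 in epithelial-like, from 1 to 8 in CD8 T-like and from 5 to 13 in fibroblast-like cells, lowest without responder 1 in each. Fibroblast-like abundance ran from −0.73 without non-responder 1 to 0.90 without non-responder 2. Smyd3 ran from −0.37 to 0.90 in epithelial-like, from −0.62 to 0.17 in CD8 T-like, from −0.53 to 0.33 in mononuclear phagocyte-like and from −0.44 to 0.0635 in fibroblast-like cells, and it turned without responder 2 (−0.37) or non-responder 1 (−0.0467) in epithelial-like cells, without non-responder 2 in CD8 T-like (0.17) and mononuclear phagocyte-like cells (0.33), and without responder 1 in fibroblast-like cells (0.0635).

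List medians that changed sign included type I interferon in epithelial-like cells (−0.32 without responder 1 to 2.19 without non-responder 1) and mononuclear phagocyte-like cells (−0.11 without responder 1 to 0.47 without responder 2), and basal keratinocyte genes (−0.40 without responder 1 to 0.0809 without non-responder 2). They also included stromal transcripts in CD8 T-like cells (−2.15 without responder 2 to 0.25 without non-responder 2), proliferation in mononuclear phagocyte-like cells (−0.0604 without non-responder 1 to 0.42 without non-responder 2), and MHC class II (−0.46 without non-responder 2 to 1.64 without non-responder 1) and resting adventitial genes in fibroblast-like cells (−0.0811 without responder 1 to 1.45 without responder 2). The myeloid list in CD8 T-like and the type I interferon list in Treg-like cells changed sign too, at values given with each class. So did the alternatively activated and stromal lists in mononuclear phagocyte-like cells.

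Among single genes, without non-responder 1 the epithelial values were highest, and ran for Isg15 from −0.27 (without responder 1) to 2.22, for B2m from −0.42 (without non-responder 2) to 1.47, for H2-K1 from −0.0616 (without non-responder 2) to 1.83 and for Cd274 from −0.85 (without responder 1) to 3.41. In CD8 T-like cells, first without non-responder 2 and then without non-responder 1, Havcr2 ran from −0.10 to 0.85, Gzmb from −0.84 to 0.75 and Ifng from −0.12 to 0.28, and Foxp3 in Treg-like cells from −0.0575 (without responder 1) to 0.13 (without responder 2). In mononuclear phagocyte-like cells, in the same order, Arg1 ran from −1.22 to 1.02, Spp1 from −2.10 to 0.39, Cd274 from −0.61 to 1.25 and Il1b from −0.35 to 0.0725, while C1qa ran from −0.19 (without non-responder 1) to 0.18. In fibroblast-like cells Col1a1 ran from −0.22 (without non-responder 2) to 0.00681, Postn from −0.29 (without non-responder 2) to 0.59, the last values of both without non-responder 1, and Acta2 from −1.30 (without responder 2) to 0.52 (without responder 1). The cause was not tested.

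Counts thinned to the smallest total of a class left the epithelial-like, mononuclear phagocyte-like and fibroblast-like classes at 0 genes, as with all counts. Alternatives that gave no value were the stromal list of CD8 T-like cells where under 5 members were tested, and Tcf7 under 10% mitochondrial UMIs, where it missed the filter on low counts.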

Other observations

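The neutrophil-like, CD4 T-like, NK-like, dendritic-like and endothelial-like classes and every value in this part were chosen after the data were seen. Ccl5, a chemokine that T and NK cells make and that attracts T cells, rose in CD4 T-like cells of responders, to 500 CPM ± 66.5 (SD, n = 2) from 105 ± 23.4 (n = 2) in non-responders (log2 2.29, SE 0.29, adjusted p 0.0211 by edgeR). Its mean without TMM scaling was also higher in classes that make little of it, at 63.4 against 13.8 CPM in neutrophil-like and 26.0 against 6.79 in epithelial-like cells, but not in endothelial-like (17.6 against 25.6) or dendritic-like cells (685 against 1963), and it was at 8582 against 3322 in CD8 T-like cells, which made up 5.31% of captured cells in responders and 1.53% in non-responders. In dendritic-like cells, which present antigen to T cells, Tnf (15.5 against 88.7 CPM) and the neutrophil attractant Cxcl2 (173 against 997) fell by 2.51 and 2.53 on the log2 scale in responders, where the neutrophil genes S100a8 (63.7 against 164 CPM, without TMM scaling) and S100a9 (76.6 against 240) also had lower means. Tnf, Cxcl2 and Cstdc4 were each among the 10 genes that set 1 or more neutrophil-like clusters apart, Clec4e is one of the fixed neutrophil markers, and neutrophil-like cells made up 19.1% of captured cells in responders and 49.7% in non-responders. In endothelial-like cells Ccl21a, which encodes a chemokine of lymphatic vessels, was found in non-responders at 2276 and 2967 UMIs and in responders at 0 and 8.

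In CD4 T-like cells Ccl5 was the 1 gene of 7873 that passed in edgeR, and 369 had an unadjusted p under 0.05. In NK-like cells Cxcl2 was the 1 gene of 6199 that passed (31.9 against 225 CPM, log2 −2.79, adjusted p 0.0105), on 37 and 18 UMIs in responders and 86 and 19 in non-responders. In dendritic-like cells 5 of 8382 genes passed, all lower in responders: besides Tnf and Cxcl2 these were the lectin receptor Clec4e (17.6 against 113 CPM, log2 −2.71), the uncharacterised Gm47662 (24.6 against 107, log2 −2.11) and the protease inhibitor Cstdc4 (4 and 2 UMIs against 45 and 45). The processing alternatives were not run for these 4 classes. The 3 of 10127 genes that passed in endothelial-like cells were lower too: Ccl21a, a gene with close paralogs, the sodium channel gene Scn3a (0 and 3 UMIs against 269 and 289) and the protease inhibitor Serpina3n (1 and 1 UMIs against 79 and 105).

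Neutrophil-like cells, the class with the largest share of cells in non-responders, gave 0 genes of 11830 in edgeR, 532 with an unadjusted p under 0.05, 2 by DESeq2 and 0 by limma voom. Ccl5 was at 67.8 CPM ± 14.9 in responders and 13 ± 1.82 in non-responders (log2 2.38, adjusted p 0.227), and the lectin receptor Clec1a (29.3 against 13.1), Rilpl2 (152 against 64.7), the stress gene Osgin1 (275 against 126) and the signalling adaptor Tbkbp1 (43.6 against 19.9) had the next smallest p on that side. On the other side were the granule protein genes Ngp (8.23 against 114) and Camp (2.72 against 59.7), the ligand gene Tnfsf9 (28.8 against 60.3), the kinase gene Uck2 (14.5 against 30.6) and the protease gene Adamdec1 (20.2 against 37.9), with an adjusted p of 0.946 for all 9. Ngp was at 35.7 and 191 CPM and Camp at 10.8 and 109 in non-responders 1 and 2, so both means rest largely on non-responder 2. T-cell transcripts from other cells were higher in neutrophil-like cells in all 18 members (median log2 1.14, 4 of them adjusted over the list alone and 0 over all genes), a list that passed at the preset correlation but not with an estimated one (adjusted p 0.437). The gene count was 0 without either responder, 603 without non-responder 1 and 5 without non-responder 2.

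Interferon gamma response genes were higher in responders at the preset correlation in neutrophil-like (median log2 0.92), CD4 T-like (0.18), NK-like (0.29), dendritic-like (0.66) and endothelial-like cells (1.15). With an estimated correlation no list passed in any of these classes, at lowest adjusted p of 0.437, 0.357, 0.874, 0.254 and 0.3325 in the same order. The median mitochondrial share in responders 1 and 2 and non-responders 1 and 2 was 2.98, 3.02, 6.19 and 6.56% in neutrophil-like, 5.99, 5.64, 8.98 and 7.57% in CD4 T-like, 5.58, 5.18, 8.24 and 7.06% in NK-like, 4.34, 4.35, 6.66 and 5.43% in dendritic-like and 5.39, 4.68, 5.68 and 5.92% in endothelial-like cells. The mean log2 level of this list in neutrophil-like cells was 7.50 and 7.01 in responders 1 and 2 and 6.92 and 5.55 in non-responders 1 and 2. Neutrophil-like cells lay in different clusters by group, mainly in clusters 3 (33.5%) and 1 (27.3%) in responders and in clusters 1 (26.9%) and 2 (24.2%) in non-responders, with non-responder 2 mainly in clusters 2 (28.2%) and 9 (25.4%), so that the list level includes any shift between them. Of the lists tested, 9 of 12 passed in neutrophil-like, 5 of 11 in CD4 T-like, 3 of 9 in NK-like, 7 of 11 in dendritic-like and 7 of 11 in endothelial-like cells. With fry the T-cell attracting chemokines of dendritic-like cells passed alone (lower, median −0.21, adjusted p 0.0244).

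The CPM values of this paragraph are without TMM scaling. T-cell transcripts from other cells had a median log2 fold change of 4.31 in dendritic-like cells, with 10 members higher adjusted over the list alone, and Cd3e there was at 11.9 CPM in responders and 0.530 in non-responders. Jcad, lower in Treg-like cells of responders, was also found at 3.42 CPM in CD8 T-like cells of responders and 21.7 in those of non-responders, and at 3.86 and 24.1 in CD4 T-like cells. Odam in epithelial-like cells was at 127 and 25.8 CPM in responders 1 and 2 and at 187 and 1232 in non-responders 1 and 2. The haemoglobin gene Hbb-bs reached 1905 CPM in CD8 T-like cells of responder 2.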
